A study of Danio rerio with 4 samples.

How the data were processed

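The study measured contacts along the major alpha/beta-globin gene domain of zebrafish (Danio rerio) blood cells by 5C, carbon-copy chromosome conformation capture. In 5C, fixed chromatin is cut and religated so that DNA ends that lay close together are joined. Pools of forward and reverse primers that each end at a junction are then annealed to this 3C library and ligated, so that each read reports 1 forward and 1 reverse primer. Per the labels' protocols, blood of larvae at 18 days post fertilisation or of adult fish was fixed with 2% formaldehyde for 10 min, and 350 ng of 3C library with 1150 ng of salmon testis carrier DNA entered each annealing. Ligated primers were amplified for 28 PCR cycles, products of 100 bp were excised from a gel, and single-end reads of 101 bp were sequenced. The 4 libraries fell into 2 groups by their developmental stage label, 2 adult and 2 larvae, and the labels describe 2 biological replicates. Whether the 2 libraries of a stage came from separate 3C templates is not given in the sources used here, and p-values measure only the spread between these libraries.

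Each library came as 1 matrix of whole-number read counts per pair of a forward and a reverse primer, as the authors deposited it, with no normalization. Per the submitters' processing notes, bcl2fastq 1.8.4 and Bowtie2 2.2.2 were used and the genome build was danRer7. Primer coordinates on chromosome 3 of danRer7 are given per the file headers. The rule by which a read was assigned to a pair, any filter on matches and the restriction enzyme are not given in the sources used here. The matrices held 77 forward and 87 reverse primers, each placed on a stretch of 30 bp, between 55888613 and 56027595, a region of 139 kb, which makes 6699 pairs. The median distance from one primer to the next was 556 bp. Pairs of 2 forward or of 2 reverse primers cannot form a product. Primers are named here by F or R for their kind and their number in the files, and distance is that between primer midpoints.

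The total count was 65450 and 38494 in adult replicates 1 and 2, and 20801 and 6539 in larvae replicates 1 and 2. A count of 0 allows up to 3 counts, which is 0.00458%, 0.00779%, 0.0144% and 0.0459% of the total in that order. These limits and the 95% exact binomial (Clopper-Pearson) intervals given for shares of 1 library cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The libraries were compared by a chi-square test of their counts over pairs, and no 2 held identical values or agreed within counting error: chi-square over degrees of freedom was 2.79 between the adult libraries and 5.18 between the larvae libraries. This excludes copies of one library but not libraries made from one template, and each library was counted as 1 replicate as labelled.

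The designs, the alternatives and the rule for named pairs were fixed before the data were examined. Pairs were tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM factors, stage as the only term and pairs kept by filterByExpr at its defaults, a minimum count of 10 and a minimum total of 15. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Counts summed over all partners of a primer (primer totals) were tested in the same way. Each read enters the total of 1 forward and of 1 reverse primer, so these totals are not independent of each other. Classes of pairs were tested with fry from limma 3.58.1 on log2 CPM with a prior count, adjusted over 13 classes. Standard errors of log2 changes were derived from the quasi-likelihood F. With 2 libraries per stage an exact permutation test of a single value cannot go below p = 0.333, so single values carry no test.

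An annotation of danRer7 was not used here, so neither globin gene block of the domain could be placed on the primers. As fixed beforehand for that case, the parts were 4 segments of equal length: segment 1 from 55888613 to 55923358 (39 primers), segment 2 from 55923359 to 55958104 (48 primers), segment 3 from 55958105 to 55992850 (44 primers) and segment 4 from 55992851 to 56027595 (33 primers). Q2-Q3 stands for pairs that join segments 2 and 3, and the other classes are named likewise. The 10 pairings of segments and 3 distance classes (under 20 kb, 20 to 60 kb, over 60 kb) were the classes. Gene names come from a RefSeq gene table of assembly GRCz12tu, used only for the order of genes. No markers of other cell types apply, since no expression was measured.

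The slope of contact decay was fitted by least squares of log2 count on log2 distance over pairs above 0 and at least 5 kb apart, 1 slope per library. Observed over expected was log2(count + 1) minus a lowess curve (fraction 0.3) on log2 distance, over pairs at least 5 kb apart, with the median per class and library. The insulation score at each gap between neighbouring primers was the mean observed over expected of pairs that span the gap with both ends within 5 primers, and for this score the lowess curve was fitted over all pairs. Libraries were compared by Pearson and Spearman correlations of log2(count + 1) over pairs, which are not independent of each other. Figures and these steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

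The pairs named are, among those past the threshold whose adult values lie both above or both below the larvae values, the 10 with the largest log2 change in each direction. The primers named are the 10 with the smallest adjusted p of the primer totals, together with the 5 strongest contacts of each stage by observed over expected. A fold against a stage with 0 reads in both libraries is a lower bound against 3 counts over the summed effective library sizes of that stage. The other stage enters as the mean of its 2 libraries, so the bound does not cover the spread between them. The tests were run on simulated counts drawn with the mean of each pair or primer over all 4 libraries, the real library sizes and the common dispersion. About as many were raised as lowered. For the comparison of 679 pairs, of which 200 were changed, 10.3% of changes of 2-fold, 56.1% of 4-fold and 100% of 16-fold were called, with 0 false calls among 479 unchanged pairs. For the 163 primer totals, of which 30 were changed, 90% of 2-fold changes and 100% of 4-fold and of 16-fold changes were called, with 0 false calls among 133. In the real data 476 of 679 pairs were called, 313 higher in adults and 163 in larvae. The simulations had fewer and balanced changes, so they do not give the rate of false calls in the real data.

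Other settings fixed beforehand were DESeq2 1.42.0 size factors, library totals in place of TMM, the DESeq2 Wald test, no filter, a minimum distance, limma on observed over expected, a replicate block, other windows and expectations, and leaving out each library in turn for pairs, primer totals, classes and observed over expected. A change of pseudocount fixed for the pair test was meant for normalized values and did not apply to counts. Settings added after seeing the data left out the 3 dominant pairs, thinned all libraries to 6539 reads, kept only pairs with reads in both stages or left out 6 primers with interchangeable counts. Others did not scale pairs by their own spread in the class test, used a window of 20 primers, left out each library in turn for the decay slope, and used summed or mean counts in place of medians and of pairs above 0.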

Results

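The data are 4 matrices of 5C read counts over 6699 primer pairs across 139 kb of zebrafish chromosome 3 (danRer7, 55888613 to 56027595), from blood cells of adult fish (2 libraries) and of larvae at 18 days post fertilisation (2 libraries). Fish red blood cells keep their nucleus, so the circulating cells still hold chromatin. The region is the major alpha/beta-globin domain, in which the embryo-larval and the adult globin genes lie in separate blocks. In the GRCz12tu gene table the order runs mpg, nprl3, the adult genes hbaa2, hbba2, ba1l, hbaa1 and hbba1, si:ch211-5k11.8, the embryo-larval genes from hbbe1.1 to hbae3, then kank2 and dock6. The end of the region at which each block lies in danRer7 was not determined here, so positions are given as coordinates and as segments 1 to 4, of equal length, from the low coordinate. Adult replicates 1 and 2 held 65450 and 38494 counts, with 2006 and 1896 pairs above 0, and larvae replicates 1 and 2 held 20801 and 6539 counts, with 1048 and 877 pairs above 0.

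The 3 primer pairs with the highest counts were the same in both stages, and why their counts were equal stays unexplained. The 3 pairs F165-R224, F165-R236 and F217-R164 had the highest counts in all 4 libraries. F165 (55943338 to 55943367) and R164 (55943182 to 55943211) lie 156 bp apart in segment 2. Their partners F217 (55966196 to 55966225), R224 (55974761 to 55974790) and R236 (55983377 to 55983406) lie in segment 3, so that F217-R164 spans 23.0 kb and F165-R224 spans 31.4 kb. The 3 pairs had 3265, 3313 and 3362 counts in adult replicate 1 and 769, 771 and 715 counts in larvae replicate 2, and in each of the 4 libraries they differed by no more than counting error. Together they took 15.2% of the counts in adult replicate 1 (95% exact binomial interval 14.9 to 15.5%), 18.5% in adult replicate 2 (18.1 to 18.9%), 24.8% in larvae replicate 1 (24.2 to 25.4%) and 34.5% in larvae replicate 2 (33.3 to 35.7%). None of the 3 passed the test between stages: log2 changes, adult minus larvae, were -0.63 for F165-R224, -0.66 for F165-R236 and -0.54 for F217-R164, with adjusted p-values of 0.135, 0.115 and 0.198 (edgeR quasi-likelihood, Benjamini-Hochberg). With all libraries thinned to one depth all 3 passed as higher in larvae (adjusted p = 0.0101, 0.00256 and 0.0202, edgeR). They did so with the replicate number as a block (3.72e-07, 8.62e-08 and 1.55e-05, edgeR), though equal replicate numbers did not pair the libraries. The share of these 3 pairs rose as the library total fell, also within each stage. Thinning keeps expected shares, so stage and depth cannot be told apart for them. R224 and R236 also had counts within counting error of each other over the other forward primers (chi-square over degrees of freedom 1.18 in adult replicate 1), so pairs with either primer are uncertain in position. The next pair by observed over expected in adults was F201-R186, 6.35 kb apart within segment 2, with 578 and 376 counts in adult and 41 and 11 counts in larvae libraries. It was higher in adults (log2 change 2.50 ± 0.44 SE, n = 2 per stage, adjusted p = 1.14e-07, edgeR). F152-R222, 36.1 kb apart across segments 2 and 3, was among the 5 strongest in both stages and was higher in larvae (log2 change -1.16 ± 0.39 SE, adjusted p = 0.00482, edgeR). It did not pass with DESeq2 (adjusted p = 0.137), without a filter (0.0512, edgeR), without the dominant pairs (0.0688, edgeR) or without either adult library. F133-R281, 74.8 kb apart across segments 2 and 4, completed the larval 5 with 127 and 39 counts, against 178 and 126 in adults (log2 change -0.82, adjusted p = 0.0677, edgeR). Among the 3 dominant pairs and F133-R281, 1 pair passed as higher in larvae with library totals in place of TMM. With limma on observed over expected the 3 dominant pairs, F152-R222 and F133-R281 turned to higher in adults (0.71 to 1.36), none past the threshold. These values are not scaled to library size, so this turn follows the greater depth of the adult libraries.

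The first comparison asked which contacts differ between the adult and the larval stage. Of the 313 contacts that were stronger in adults, 115 lay within segment 2, which held 214 of the 679 tested pairs. The part of tested pairs that was adult-higher was larger in Q1-Q2 (52 of 79) and Q1-Q3 (22 of 37). Of the 10 with the largest change, 7 lay within segment 2, at primers between 55943182 and 55957405. All 10 had 0 reads in both larvae libraries, so their order mostly follows adult counts. The pair with the largest change was F199-R198, 0.664 kb apart (55956682 to 55956711 and 55956018 to 55956047), with 1495 and 995 counts in the adult libraries and 0 in both larvae libraries, at least 249-fold higher in adults. The rule for these named pairs set no minimum distance, so they include pairs closer than the 5 kb used for decay, such as this one. F165-R164 (0.156 kb) and F188-R186 (0.823 kb) also joined primers less than 1 kb apart. Whether the reads of pairs this close reflect folding of the region was not tested. F201-R164 (460 and 202 counts in adults), F199-R164 (371 and 185) and F165-R164 (292 and 184) were also at 0 in both larvae libraries, and were at least 62.8-fold, 53.6-fold and 47.3-fold higher in adults. Larvae-higher contacts lay in all 4 segments and included F275-R182, which joined segment 4 (55999271 to 55999300) to segment 2 (55950359 to 55950388) over 48.9 kb, with 156 and 23 counts in the larvae libraries and 0 in both adult libraries, at least 169-fold higher in larvae.

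Of 679 pairs tested with the edgeR quasi-likelihood test, 476 (70.1%) differed between stages after Benjamini-Hochberg adjustment, 313 higher in adults and 163 higher in larvae. The median log2 change of all tested pairs was 1.08, adult minus larvae, and it was 0.91 with library totals and 1.15 with DESeq2 size factors. It was 3.10 without a filter, 2.18 for pairs at least 5 kb apart, 1.43 without the dominant pairs and -0.19 for pairs with reads in both stages, so this level depends on the pairs tested. In 569 of the 679 tested pairs the adult and larvae values did not overlap. Of the 313 pairs higher in adults, 241 had no read in either larvae library, and of the 163 pairs higher in larvae, 79 had no read in either adult library. All 10 pairs named in each direction were of this kind. Among the adult-higher ones, F208-R198 and F208-R178 reached from segment 2 into segment 3 (at least 35.6-fold and 29.6-fold). F261-R272 joined segments 3 and 4 over 7.33 kb (at least 32.3-fold), and F168-R164, F188-R198 and F188-R186 lay within segment 2 (at least 31.8-fold, 28.5-fold and 25.5-fold). Their adjusted p-values ran up to 1.3e-10 (F188-R186, edgeR). Among the larvae-higher ones, F175-R176 (at least 125-fold), F273-R272 (at least 111-fold), F121-R123 (at least 84.2-fold) and F275-R272 (at least 74.0-fold) joined primers less than 1 kb apart. F210-R207 (at least 80.3-fold) and F221-R209 (at least 78.1-fold) lay within segment 3, F234-R191 (at least 93.1-fold) and F221-R178 (at least 90.3-fold) joined segments 2 and 3, and F141-R55 (at least 85.3-fold) joined segments 1 and 2. Their adjusted p-values ran up to 1.64e-12 (F221-R178, edgeR). These folds use the mean of the 2 larvae libraries, which could differ widely. F275-R272 had 89 and 3 counts (5078 and 500 CPM), and F221-R178 had 20 and 34 (1141 and 5662 CPM). The fold in the lower library alone is smaller than the bound given. Among the 359 tested pairs with reads in both stages, 151 differed, 61 higher in adults and 90 higher in larvae. This choice of pairs leaves out more adult-higher than larvae-higher pairs (241 and 79), so its balance between stages follows from the choice. Without larvae replicate 1 the adult-higher pairs numbered 205, and without adult replicate 2 the larvae-higher pairs numbered 106.

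**Figure D1:**
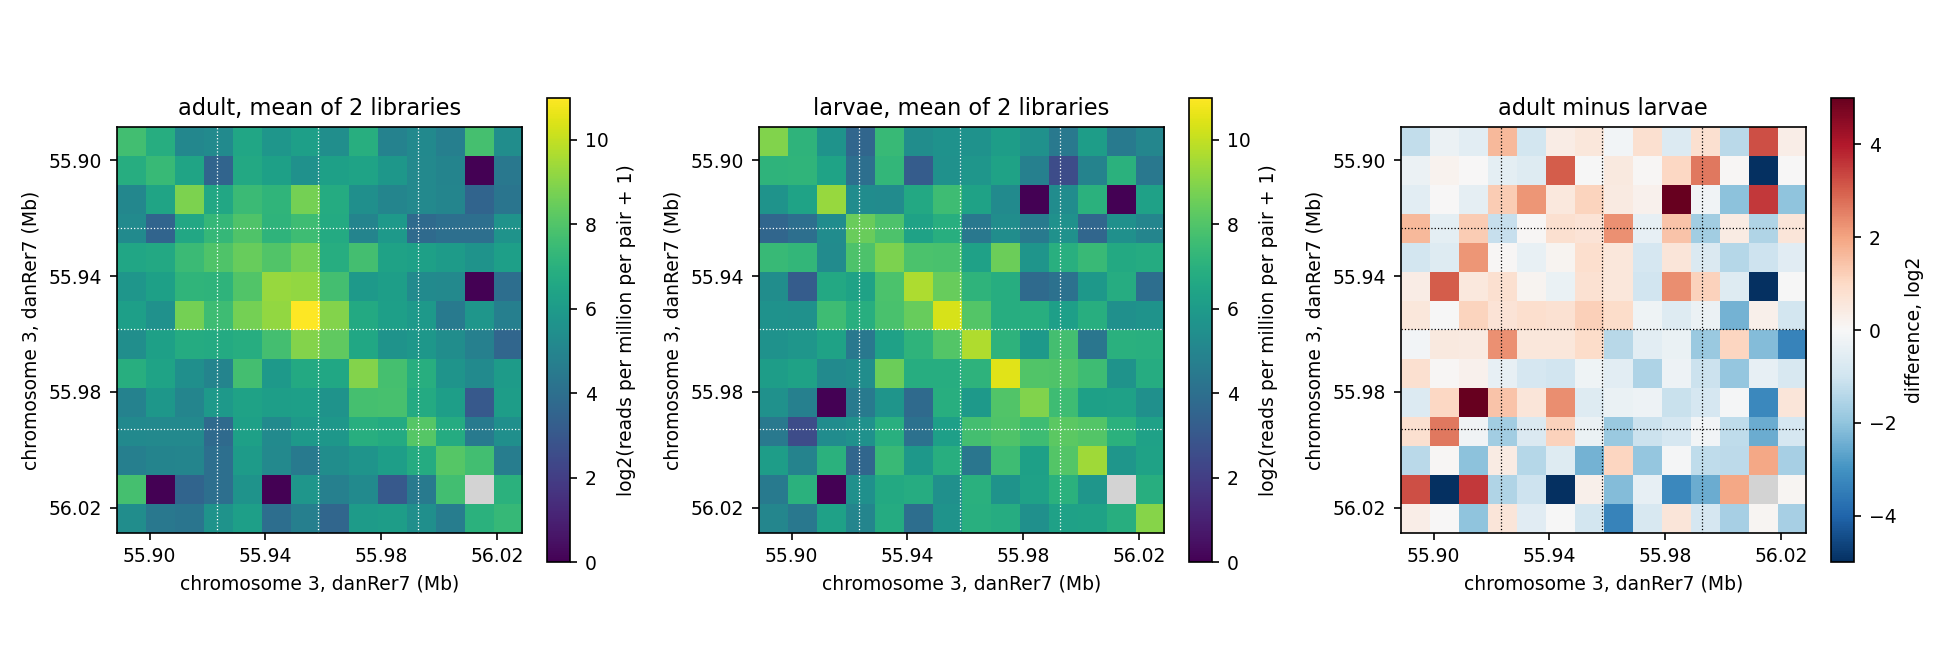
Mean CPM (reads scaled to library size) per primer pair in 10 kb bins along chromosome 3 (danRer7, Mb on both axes), on a log2 scale with 1 added, for adults and larvae (each the mean of 2 libraries, 3 dominant pairs left out) and the difference adult minus larvae. Dotted lines mark the 4 segments and grey marks a bin without pairs; red bins toward the upper end of segment 2 show the adult-higher contacts within segment 2, and blue prevails among bins that join segments 3 and 4.

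The second comparison asked which primers as a whole had more or fewer reads in one stage. The adult-higher primers lay mostly in segment 2 and the larvae-higher primers mostly in segments 3 and 4. R198 (55956018 to 55956047) took 7.28% ± 0.27 of the counts in adults and 0.966% ± 0.44 in larvae (SD, n = 2 each), and F199 (55956682 to 55956711) took 6.67% ± 0.065 and 1.63% ± 0.13. In a stretch of 3.76 kb in segment 4, R268 (55995544 to 55995573), F273 (55998738 to 55998767), R274 (55999168 to 55999197) and F275 (55999271 to 55999300) all had a larger share in larvae, such as 0.819% ± 0.099 against 0.147% ± 0.0088 for R268.

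Of 163 primer totals tested, 90 differed between stages (edgeR quasi-likelihood, Benjamini-Hochberg), 42 higher in adults and 48 higher in larvae. In segment 2, 24 primers were higher in adults, 7 were higher in larvae and 17 did not pass, with a median log2 change of 0.63. In segment 1 these numbers were 11, 5 and 22 (median 0.27), in segment 3 they were 5, 18 and 21 (median -0.46), and in segment 4 they were 2, 18 and 13 (median -0.82). The median of segment 1 turned to -0.40 with only pairs that had reads in both stages, and that of segment 3 was -0.20 with partners at least 5 kb away. The 10 primers with the smallest adjusted p had values from 0.000134 to 0.000214 (edgeR). R198 changed by 2.81 ± 0.27 on the log2 scale (SE), F199 by 1.99 ± 0.22 and F190 (55952827 to 55952856) by 1.67 ± 0.18, all higher in adults. The larvae-higher ones were F275 (-3.03 ± 0.32), R268 (-2.53 ± 0.23), R274 (-2.47 ± 0.23), F273 (-2.01 ± 0.19), F311 at 56027257 to 56027286 (-1.81 ± 0.19), R281 at 56004776 to 56004805 (-1.68 ± 0.15) and F141 at 55933653 to 55933682 in segment 2 (-1.34 ± 0.14). With only pairs that had reads in both stages, 52 primers differed, and R274, F275 and F141 did not pass (adjusted p = 0.836, 0.0816 and 0.241, edgeR). Without adult replicate 1 or adult replicate 2, 46 and 54 primers differed.

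**Figure D2:**
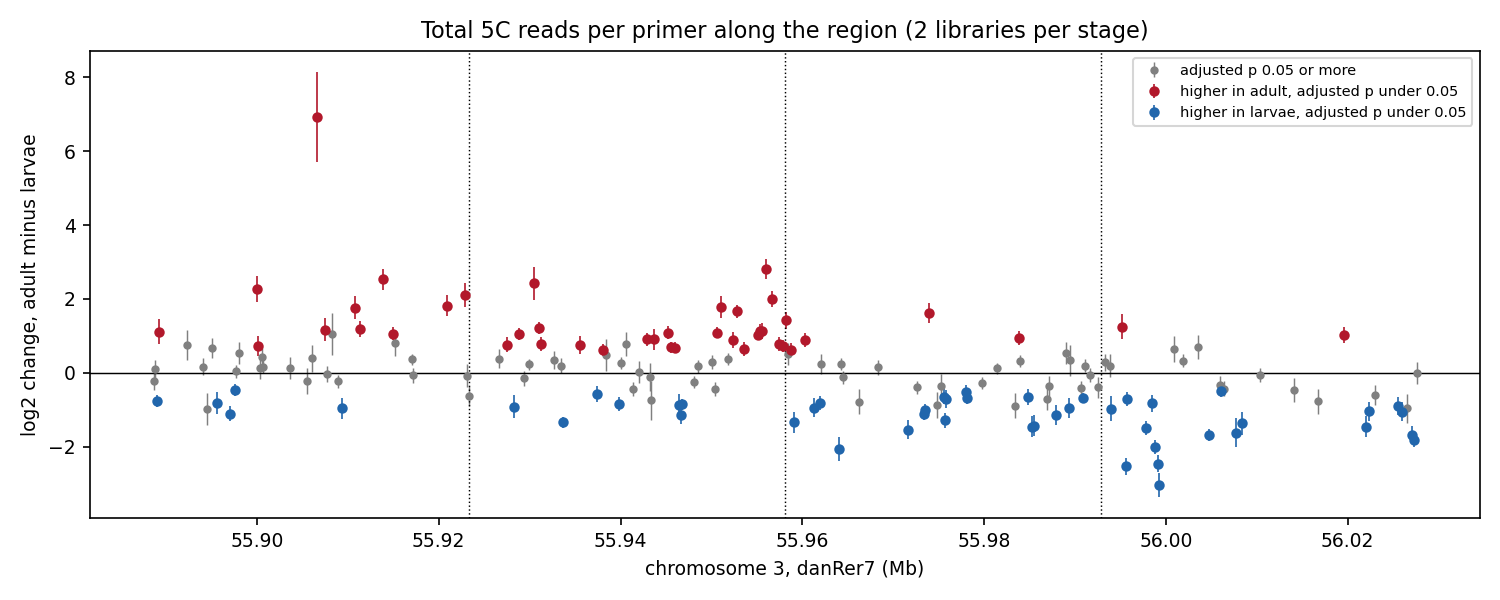
Log2 change of each primer's total reads, adult minus larvae, against its position on chromosome 3 (danRer7, Mb), with bars of 1 SE (n = 2 libraries per stage). Red and blue points passed an adjusted p of 0.05 (edgeR quasi-likelihood); the red points gather in segment 2, where 24 primers were higher in adults, and the blue points in segments 3 and 4, where 18 in each were higher in larvae.

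The third comparison took up the question in the study's title, whether the 2 parts of the domain are separate in structure, as far as equal segments of the region can address it. Contacts within segment 2 made up 35.4% ± 1.15 of all counts in adults and 19.1% ± 1.88 in larvae (SD, n = 2 each). The rise did not hold within every 10 kb bin: with the dominant pairs left out, mean CPM per pair was 2875 in adults and 1271 in larvae within the bin from 55948613 to 55958612. It was higher in larvae within the bins from 55928613 (352 and 461) and from 55938613 (638 and 799). Between different bins it was higher in adults: 260 and 238 for those from 55928613 and 55938613. It was 410 and 226 for those from 55928613 and 55948613, and 587 and 344 for those from 55938613 and 55948613. Contacts of segment 1 with segment 2 (9.36% ± 0.58 in adults, 5.49% ± 1.19 in larvae) and with segment 3 (4.22% ± 0.19 and 2.56% ± 0.40) were also a larger share in adults. Contacts within segment 1 (3.66% ± 0.14 in adults, 4.62% ± 0.81 in larvae), within segment 3 (6.67% ± 0.040 and 10.7% ± 0.59), within segment 4 (2.59% ± 0.086 and 4.97% ± 0.56), of segment 3 with segment 4 (4.22% ± 0.16 and 6.95% ± 0.57) and of segment 2 with segment 4 (2.64% ± 0.027 and 4.45% ± 0.32) were larger shares in larvae. In these 8 classes the 2 libraries of a stage did not overlap with those of the other, with or without the 3 dominant pairs. Contacts of segment 2 with segment 3 were 29.4% ± 1.85 in adults and 39.3% ± 6.59 in larvae, but this class holds the dominant pairs, and without them its share was 15.1% ± 0.14 and 13.8% ± 0.98. Pairs under 20 kb took 54.6% ± 1.25 in adults and 44.1% ± 4.14 in larvae, which became 65.6% ± 0.32 and 62.7% ± 0.22 without the dominant pairs.

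In the fry test of limma, 10 of the 13 classes passed, 9 with the direction higher in adults and Q4-Q4 with the direction higher in larvae (adjusted p = 0.0216). With the replicate number as a block 0 of the 13 classes passed (lowest adjusted p = 0.110, fry). The block fits a further term to the same 4 libraries, which leaves less information on their spread and so less power. The test is against no change, so a class that passed need not lie above the level of all pairs. Q2-Q2 had a median log2 change of 1.75 over 214 pairs, of which 115 were higher in adults and 35 in larvae (adjusted p = 0.00572, fry). The median was larger in Q1-Q4 (3.41), Q1-Q2 (3.28, with 52 of 79 pairs higher in adults), 20 to 60 kb (3.03) and Q1-Q3 (2.98), and smaller under 20 kb (0.84) and over 60 kb (0.68), which all passed as higher in adults. Q4-Q4 had a median of -0.68 over 38 pairs, 11 higher in adults and 15 in larvae. Q1-Q1 passed as higher in adults with a mean log2 change of 0.30 and a median of -0.32. Among the 9 classes that passed as higher in adults, the mean share of counts was larger in larvae for Q1-Q1, Q1-Q4 (1.83% in adults and 1.87% in larvae), Q2-Q3 (29.4% and 39.3%), 20 to 60 kb (38.6% and 48.4%) and over 60 kb (6.79% and 7.49%). Without the dominant pairs the shares were 2.21% and 2.66% for Q1-Q4, 26.2% and 26.6% for 20 to 60 kb, and 8.16% and 10.6% for over 60 kb. That of Q2-Q3 then turned to larger in adults (15.1% and 13.8%). With all libraries thinned to one depth, over 60 kb did not pass (adjusted p = 0.0618, fry). Q2-Q4, Q3-Q3 and Q3-Q4 did not pass (adjusted p = 0.921, 0.639 and 0.612, fry), and for Q2-Q4 and Q3-Q3 the test's direction was adult while mean and median were below 0. The test scaled each pair by its own spread, and pairs at 0 in both libraries of a stage have a spread near 0 in that stage. How much weight these pairs took in the fit of all 4 libraries was not measured. Without either adult library all 13 classes were called higher in adults, while without larvae replicate 1 or 2 only 1 class was called higher in adults and 9 and 12 classes were called higher in larvae. Without the scaling by spread, 5 classes passed, all higher in adults (Q1-Q2, Q2-Q2, Q2-Q3, under 20 kb and 20 to 60 kb), and Q4-Q4 did not (adjusted p = 0.0712, fry). These calls were not kept when either adult library was left out. In unscaled fits with 1 library left out, each class kept the direction of its mean log2 change (1.49 to 1.66 for Q2-Q2). The turns of direction in the scaled fits therefore followed the scaling.

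**Figure D3:**
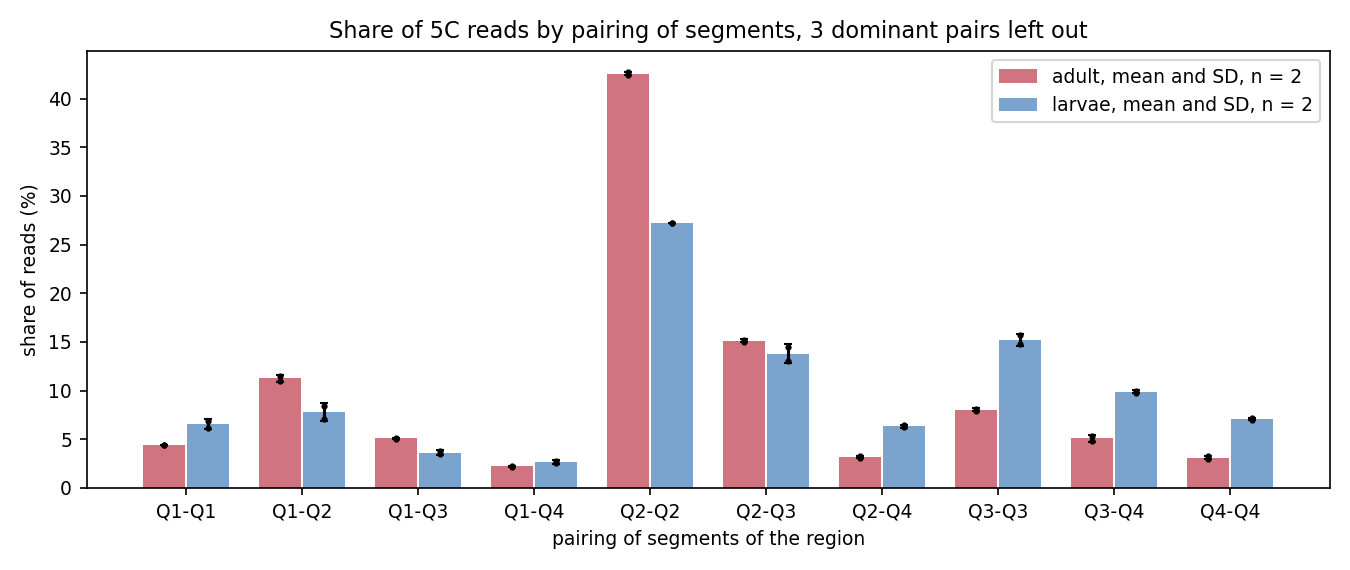
Share of reads (%) in each of the 10 pairings of segments, with the 3 dominant pairs left out; bars are means, error bars the SD and points the 2 libraries of each stage. Q2-Q2 was larger in adults, 42.6% against 27.2% in larvae, and Q3-Q3, Q3-Q4, Q2-Q4 and Q4-Q4 were larger in larvae.

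Contacts grew weaker with distance in both stages. Mean CPM per pair fell from 1052 and 1078 under 1 kb to 40.5 and 41.2 at 100 to 140 kb in adult replicates 1 and 2, and from 1405 and 1217 to 47.0 and 38.7 in larvae replicates 1 and 2, with the dominant pairs left out. Over pairs above 0 and at least 5 kb apart, the slope of log2 count on log2 distance was -0.24 ± 0.0071 in adults and -0.07 ± 0.029 in larvae (SD, n = 2 each). This slope leaves out pairs at 0, which were more frequent at long distance and in larvae, and the slope of the mean over all pairs per distance class was -0.80 in adults and -0.68 in larvae. At 60 to 100 kb the 2 larvae libraries (58.5 and 57.7 CPM per pair) lay above the 2 adult libraries (43.0 and 42.1 CPM).

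**Figure D4:**
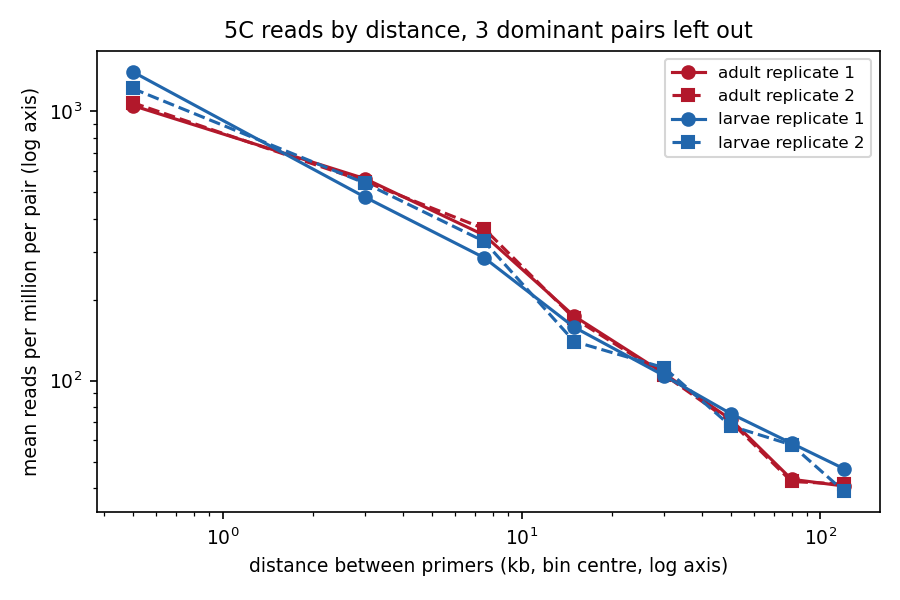
Mean CPM per primer pair (log axis) against the distance between primers (kb, centre of each distance class, log axis) for each of the 4 libraries, 3 dominant pairs left out. The 4 curves fall from 1052 to 1405 CPM under 1 kb to 38.7 to 47.0 CPM at 100 to 140 kb.

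Set against the level expected from distance, contacts within segment 2 were the highest of the 10 pairings in adults. The median observed over expected of Q2-Q2 was 2.38 ± 0.54 on the log2 scale in adults and 0 in larvae (SD, n = 2 each). It was 0.75 in adults and -0.24 in larvae with primer effects removed, and 0.52 and 0 with 10 times the pseudocount. The expected level was near 0, so the size of this median depends on depth, and the larval value of 0 is its floor. For each of the other 9 pairings of segments the median was 0 or just below 0 in all 4 libraries, since most pairs had no read, so this median did not separate these classes. From summed counts without the dominant pairs, an estimate added after seeing the data, Q2-Q2 was 1.17 ± 0.015 in adults and 0.73 ± 0.13 in larvae, the highest of the 10 pairings in both stages, and Q3-Q4 was -0.95 ± 0.11 in adults and 0.22 ± 0.020 in larvae. In the medians with primer effects removed Q2-Q2 kept this rank in adults only. In larvae Q1-Q1 was the highest (0.027), and only Q2-Q3 (-0.30) and Q2-Q4 (-0.25) lay below Q2-Q2. Contacts within segments against those between segments differed by 0.07 ± 0.011 in adults and by -0.09 ± 0.056 in larvae in these summed counts, by -0.01 and 0 in the medians, and by 0.26 ± 0.0055 and 0.06 ± 0.029 in the medians with primer effects removed.

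The lowest insulation score, where the fewest contacts cross a position relative to distance, lay at 55990768 near the end of segment 3 in both adult libraries, with scores of -1.98 and -1.51, but in adult replicate 2 the next lowest position had -1.50. In both larvae libraries it lay at 55907634 in segment 1 with a score of 0, a value shared by 2 and 3 of the 155 positions, so the larval minimum marks windows without reads. With windows of 3 primers the adult minimum moved to 55907081, and with windows of 20 primers, added after seeing the data, it moved to 55906318.

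Libraries of one stage resembled each other more than those of the other stage. Over the 6699 pairs, Pearson's r of log2(count + 1) was 0.965 between the adult libraries, 0.846 between the larvae libraries, and 0.374 to 0.424 across stages. Spearman's rho was 0.959, 0.842 and 0.308 to 0.315. Of the 2508 pairs with a read in any library, 493 had reads in all 4, 1244 in both adult libraries and neither larvae library, and 307 in both larvae libraries and neither adult library.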

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

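Of the alternatives, those that leave out the 3 dominant pairs or 6 interchangeable primers, thin all libraries to one depth, keep pairs with reads in both stages, leave pairs unscaled in the class test, use a window of 20 primers, leave out each library for the decay slope, or use summed or mean counts were chosen after seeing the data. The number of differing pairs (476 at first) stayed between 410 and 492 with library totals, DESeq2 size factors, the DESeq2 Wald test, the replicate block, thinning, and without the dominant pairs or the interchangeable primers. The thinned fit kept the pairs that the filter had chosen on full counts, so thinning did not remove the effect of depth on that choice. The number of differing pairs was 365 from 5 kb, where 476 pairs were tested. It was 1340 without a filter (914 higher in adults, 426 in larvae), where 2508 pairs were tested. It was 281 with limma on observed over expected (33 higher in larvae), which is not scaled to library size, and there 14 called pairs had the opposite sign. It was 151 among pairs with reads in both stages (61 and 90). Primer totals, 90 at first, gave 71 to 91 calls under the other settings with all 4 libraries and 52 calls there (24 higher in larvae). Of these 90 primers 8 turned sign with partners at least 5 kb away, where 61 of the 75 calls were shared, 9 did so with pairs in both stages and 1 without the interchangeable primers. With 1 library left out, differing pairs ranged from 330 to 486 (205 to 314 higher in adults, 106 to 172 in larvae) and primers from 46 to 111 (26 to 52 and 20 to 59), and the lone library of a stage was assumed to vary like the other stage.

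In the class test, calls ranged from 10 to 13 with 1 library left out, 1 to 13 as higher in adults and 0 to 12 as higher in larvae. With pairs in both stages 5 classes passed (1 higher in adults, 4 in larvae), and with unscaled pairs 5 (all adult, 0 larvae). Classes called higher in larvae numbered 2 with library totals, 3 without the dominant pairs or with thinning, and 0 without a filter, with observed over expected values or without the interchangeable primers. The mean log2 change turned sign with pairs in both stages for Q1-Q1 (-0.60), Q1-Q3 (-0.19), Q1-Q4 (-1.19), Q2-Q4 (0.19), 20 to 60 kb (-0.44) and over 60 kb (-0.42). With thinning it did so for Q1-Q1 (-0.10). Without a filter it did so for Q2-Q4 (0.20), Q3-Q3 (0.21), Q3-Q4 (0.18) and Q4-Q4 (0.22), and with observed over expected values for Q2-Q4 (0.93), Q3-Q3 (1.31), Q3-Q4 (0.96) and Q4-Q4 (0.47). Without the dominant pairs it did so for Q3-Q3 (0.037) and Q3-Q4 (0.10). It did so without the interchangeable primers for Q3-Q4 (0.047). The Q2-Q3 share, adult minus larvae, became 1.36 percentage points without the dominant pairs, and that of Q1-Q4 ranged from -0.247 to 0.167 with 1 library left out. Under limma on observed over expected F217-R164 (1.36), F165-R224 (1.28), F165-R236 (1.25), F152-R222 (0.71) and F133-R281 (1.07) turned to higher in adults, none past the threshold. Observed over expected is not scaled to library size, and its expected level was near 0. Turns to higher in adults under it therefore follow the greater depth of the adult libraries. The cause of the other turns was not tested.

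The same replicate numbers in both stages did not pair the libraries: deviations of same-numbered libraries correlated at 0.03 over 493 pairs. With the replicate number as a block, 456 pairs (306 and 150) and 71 primers (35 and 36) differed and 0 of 13 classes passed (0 adult, 0 larvae), while the 3 dominant pairs passed as higher in larvae.

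The decay slope in adults was -0.18 with primer effects fitted, -0.21 from 10 kb, -0.26 with no minimum distance, -0.38 with pairs at 0 kept, -0.16 thinned and -0.80 from class means. In larvae it was 0.00476 from 10 kb and -0.14, -0.16, -0.023 and -0.68 under the last 4 in turn. Adult minus larvae was -0.17 at first and -0.12, -0.21, -0.12, -0.23, -0.14 and -0.12 under these 6 in turn. Leaving out 1 library gave -0.24 to -0.23 in adults, -0.09 to -0.05 in larvae and -0.19 to -0.15 for the difference. Median observed over expected of Q2-Q2 in adults was 2.38 ± 0.54 (SD, n = 2) at first, moved by less than that SD with medians in distance bins, and was 2.39 from 10 kb, 0.75 with primer effects removed, 0.52 with 10 times the pseudocount and 1.17 from summed counts. In larvae it was 0 except for -0.24 with primer effects removed and 0.73 from summed counts. Observed over expected within minus between segments was 0.26 in adults and 0.064 in larvae with primer effects removed, and 0.071 and -0.088 from summed counts. With 1 library left out it ran from -0.012 to 0 in adults and stayed at 0 in larvae.

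The insulation minimum with a window of 3 lay at 55907081 in both adult libraries and at 55894299 and 55893219 in larvae replicates 1 and 2. With a window of 8 it moved in larvae replicate 1 to 56015410, and with primer effects removed it moved to 55965318 in both larvae libraries. With medians in distance bins it lay at 55987567 and 55988504 in adult replicates 1 and 2, and with a window of 20 at 55906318 in both. Pearson's r within adults, within larvae and across stages was 0.960, 0.824 and 0.309 on observed over expected, 0.961, 0.824 and 0.320 from 5 kb, and 0.933, 0.658 and 0.490 over pairs above 0 in all 4 libraries. Depth limits the larvae most: at 6539 counts, a pair at 0 in larvae replicate 2 may hold up to 0.0459% of its reads.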

Other observations

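In this part the tests of primers R224 and R236, of neighbouring exclusive pairs with both ways of shuffling, of neighbouring primers, and of pairs with reads in both stages had their outcomes set down before their results were seen, and the other tests and the runs of primers were chosen after. Some primers that changed in the same direction lay side by side, while 27 of the 46 runs of such primers held a single primer. The length of runs was not tested, and neighbouring forward and reverse totals share the reads of their common pairs. The longest run held 11 neighbouring primers higher in adults, from R189 to F203 (55952347 to 55958214, 5.87 kb), with a median log2 change of 1.13. Another 4 primers from F104 to F112 (55910785 to 55914944) in segment 1 were higher in adults (median 1.47), as were 4 from R166 to F173 (55943690 to 55946041, median 0.79). The longest larvae-higher run held 7 primers from R268 to F275 (55995544 to 55999300, 3.76 kb) with a median of -2.01, and 5 primers from R227 to F232 (55975519 to 55978145) had a median of -0.68.

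The 3 dominant pairs took 15.2 to 34.5% of the reads of a library with nearly equal counts. Reads of one product shared by F217-R164 and F165-R224 through near-identical forward primers are argued against, since counts of F165 and F217 over other reverse primers disagreed (lowest chi-square over degrees of freedom 13.8 in the 3 libraries with 10 or more such partners). R224 and R236, 8.62 kb apart, may share a sequence, since their counts over forward primers other than F165 also differed by no more than counting error (chi-square over degrees of freedom 1.18 in adult replicate 1). Of 5551 combinations of 2 primers of a kind in that library, with a median of 24.5, 3 lay below 2: R220 with R233 (0.64, 7.18 kb apart), F184 with F196 (0.81, 4.99 kb apart) and R224 with R236 (1.11 over all forward primers). Globin genes are repeated copies, primer sequences were not used here, the equal counts of F217-R164 stay unexplained, and no biological explanation was tested.

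Many pairs were seen in both libraries of one stage and in neither of the other. Lower read depth of the larvae libraries is argued against: of pairs with 10 or more reads in adult replicates 1 and 2, 58.6% and 54.0% were at 0 in both larvae libraries, against 5.23% and 6.49% (upper limits 11.5% and 12.1%) at the same counts from larvae replicate 1 to the shallower larvae replicate 2. Both libraries of a stage could have drawn on one limited set of ligation products, which the counts leave open: at most 6.15% of pairs with 10 or more reads were at 0 in the other library of the stage, against 13.9% or more across stages, which a true stage difference would give as well. Of 455 neighbouring exclusive pairs (same forward primer, adjacent reverse primers), 75.2% belonged to the same stage, against 68.5% after shuffling within distance classes (permutation p = 0.0008, 10000 shuffles). Stage effects of single forward primers may give this excess, as shuffling also within forward primers gave 73.6% (permutation p = 0.1746), so a change over whole stretches cannot be told apart from them, and stage itself stays an open explanation.

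Primer totals were higher in adults in segment 2 and in larvae in segment 4, with median log2 changes 1.45 apart. The gap was 1.28 with all libraries thinned to one depth, but this does not decide whether depth plays a part. Random thinning keeps the expected share of each primer, and the log2 changes are scaled to library size. Exclusive pairs alone are argued against, since the gap was 0.98 with only pairs that had reads in both stages. Effects of single primers without regard to position could not be settled: the log2 changes of neighbouring forward primers correlated (r = 0.41, permutation p = 6e-05) and those of neighbouring reverse primers less so (r = 0.148, permutation p = 0.06037). A difference in chromatin contacts between adult and larval blood cells, or in the makeup of the blood at each stage, may underlie the gap and was not tested.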
